A study of Rattus norvegicus with 6 samples.

How the data were processed

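Gene expression was measured by RNA sequencing of polyA-selected RNA in cultures that the labels describe as neonatal rat cardiomyocytes, the beating muscle cells of the newborn heart. Per the labels' protocols the cells came from pups of 1 to 3 days, were treated with 500 µM palmitic acid, a saturated fatty acid, for 24 h, and carried an adenoviral vector, harvested after 48 h. The labels give 2 groups of 3 libraries, Ad-GFP (a vector with green fluorescent protein, the control) and Ad-RNF128 (a vector labelled with the ubiquitin ligase RNF128). The treatment protocol of each label writes the overexpressed gene once as RNF28, an alias of Trim63 in the reference gene table, and once as RNF128. It was taken as RNF128, as the titles give it. Replicate numbers 1 to 3 come from the sample titles. The labels name no separate animals, batches or pairing. P-values therefore measure only the spread between these samples, which may be technical.

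The deposited values are counts of reads per gene, one table per library, with Ensembl gene IDs beside gene names. Per the submitters' processing notes, HISAT2 (no version listed), HTSeq 0.13.5 and the rat build mRatBN7.2 were used, and the labels' protocols name 1.5 µg of input RNA. The strand setting of the counting is not given in the sources used here, so antisense and overlapping genes cannot be told apart. Ad-GFP replicate 1 was treated as an expected count column because its top row holds 344.5. That is the single value in the deposited tables that is not whole, and it was rounded. All 6 tables hold the same 18077 rows, and 106 rows repeat an ID that occurs earlier. Repeated rows were kept as separate features, and a listed gene was read from its row with the highest mean count. Gene names were taken from the tables, since the reference gene table used here pairs no Ensembl IDs with names, and no coordinates, lengths or GC contents were used.

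Library totals ran from 16352843 to 21708973 counts. Intervals and floors cover counting error only, at 95% confidence, and the floor for a gene without reads is 3 counts. CPM values, a gene's count times 1000000 over the library total, were computed from the deposited counts. Differential expression was tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr, TMM scaling, a quasi-likelihood F-test on the counts, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are Ad-RNF128 over Ad-GFP. The SE given after ± for a log2 change was derived from that change and its F statistic. For genes with few control reads it can be smaller than the counting error. A total of 31 gene lists were fixed before the data were examined, together with the test, the alternatives and the rule for named genes. The 29 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of members past the threshold are given over all genes and adjusted over the list alone.

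The rule names Rnf128, then the 8 genes with the largest rise and the 8 with the largest fall. These needed an adjusted p under 0.05, a mean CPM of at least 5, groups that do not overlap and a gene symbol. It then names the 3 members with the smallest p of each list that passed its test or had at least 3 members past the threshold. Where fewer genes pass, those with the smallest p are given as values. Leaving out each library in turn was among the alternatives fixed then. Because Ad-GFP replicate 1 stood far from all other libraries, the comparison without it is reported beside the one with all 6 libraries. The decision to give that comparison this room, to apply the naming rule to it and to rerun the alternatives on it was made after seeing the data. With 2 control libraries left, its spread is pooled over both groups.

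The alternatives were median-of-ratios size factors, library totals only, DESeq2 1.42.0, limma-voom, no low-count filter, and a stricter filter of 10 counts in 3 libraries with a mean CPM of 1. Further ones were a block for the replicate number, leaving out mitochondrial genome genes or Rnf128 before library sizes, a log2 change of at least 1, and an adjusted p under 0.01. Single comparisons of Rnf128 and Rnf157 used an exact two-sided permutation test.

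The fits were tested on simulated data, with 200 genes changed among the real genes. In the comparison without Ad-GFP replicate 1, with 13173 genes, 90% of the genes changed 2-fold and 99% of those changed 4-fold were recovered, and 10.8% of all calls were false. The real comparison called 56.9% of its genes, far more than were changed here, so the share of false calls there may differ. In the comparison of all 6 libraries, with 12863 genes and its own spread, 0 of the 100 genes changed 2-fold and 0 of the 100 changed 4-fold were recovered. That simulation gave the spread to every library alike, whereas in the data Ad-GFP replicate 1 stood apart. In both simulations the list raised 2-fold was called by camera and 0 other lists were. The simulated genes varied independently of each other, so this does not show how often camera calls lists falsely when genes move together. In the real data the mitochondrial genome list had an estimated correlation of 0.79 over all 6 libraries and 0.676 without Ad-GFP replicate 1.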

Results

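RNA was sequenced from 6 libraries of palmitate-treated cultures that the labels describe as neonatal rat cardiomyocytes. Of these 3 were labelled Ad-GFP and 3 Ad-RNF128, and reads were counted per gene. Totals were 16352843, 18053154 and 21332585 counts in Ad-GFP replicates 1, 2 and 3, and 17099149, 21708973 and 19253718 counts in Ad-RNF128 replicates 1, 2 and 3. The design asks which genes change when RNF128, a transmembrane RING-type ubiquitin ligase, is overexpressed.

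The overexpressed gene was examined first. Rnf128 (ENSRNOG00000055721) had 0, 2 and 1 counts in Ad-GFP replicates 1 to 3 and 1, 3 and 1 counts in Ad-RNF128 replicates 1 to 3. The ratio of the groups was 1.6, with a counting interval of 0.311 to 10.3, and the exact permutation p was 0.5, where the smallest possible is 0.1. A rise in these few counts was therefore not detected, and no library held Rnf128 above 0.138 CPM. The counts on the rat gene thus do not bear out the label of the 3 Ad-RNF128 libraries. Another RING-type ligase gene, Rnf157 (ENSRNOG00000049862), was at 22.3, 39.6 and 40.4 CPM in Ad-GFP and at 1920, 2550 and 2090 CPM in Ad-RNF128. It ranked between 15 and 34 among all genes of the latter libraries. Its exact permutation p was 0.1, the smallest possible. All directions given here are for the libraries labelled Ad-RNF128 against those labelled Ad-GFP, and rest on a label that Rnf128 does not bear out.

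**Figure D1:**
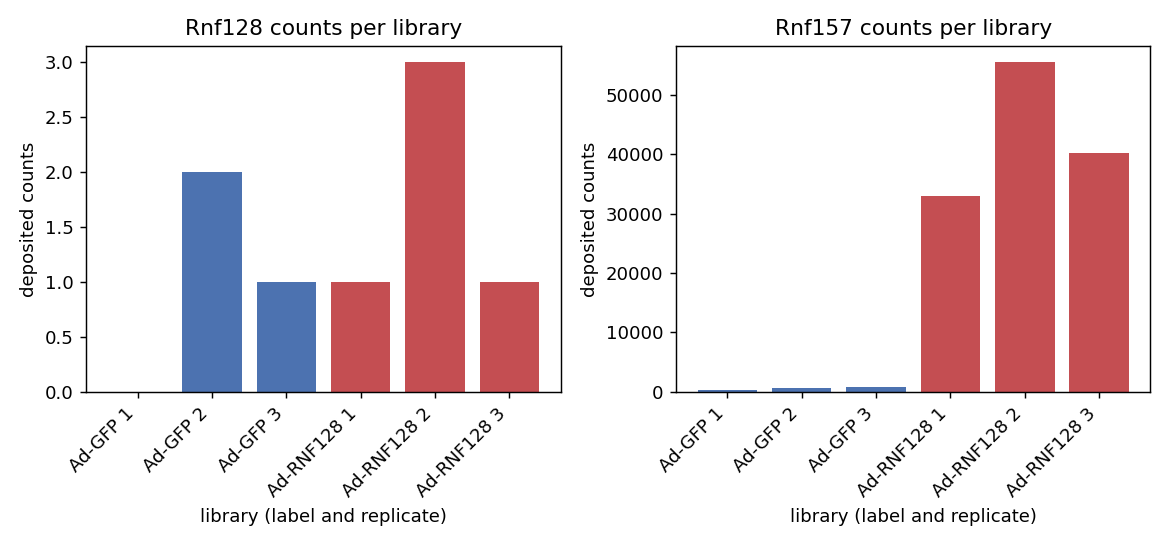
Deposited counts (vertical axes, linear, different scales) of Rnf128 (left) and Rnf157 (right) in each of the 6 libraries, Ad-GFP in blue and Ad-RNF128 in red, 1 bar per library. Rnf128 stays between 0 and 3 counts, while Rnf157 lies between 364 and 862 counts in Ad-GFP and between 32883 and 55428 in Ad-RNF128.

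One control library differed from all others. Ad-GFP replicate 1 had Spearman correlations of 0.776 to 0.818 with the other 5 libraries, and had 3551 genes without a read against 1190 to 2288 in the others. Ribosomal protein genes took 14.7% of its counts, against 3.55% to 5.48% elsewhere, and mitochondrial genome genes took 0.951%, against 3.08% to 5.35%. Several interferon-induced genes were high in it. Irf7 was at 3780 CPM, against 14.5 and 14.0 in Ad-GFP replicates 2 and 3, while Mx1 was at 0.917 CPM in it. Its fibrillar collagen level was low, with Col1a1 at 1100 CPM against 17700 and 18300.

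Over all 6 libraries no gene passed the threshold, and those with the smallest p are given as values. Rnf157 had a log2 change of 5.48 ± 0.41 (SE), the interferon-induced GTPase gene Gbp4 7.05 ± 0.67, and the chemokine gene Ccl2 4.91 ± 0.41, each with an edgeR adjusted p of 0.073. Ifi44l, Samd9, Cd28, Igtp and Tmprss2 had the same adjusted p. Igtp, another interferon-inducible GTPase gene, was at 6.4, 12.4 and 12.1 CPM in Ad-GFP and 140.8, 156.0 and 135.4 CPM in Ad-RNF128. Of 12863 genes tested with edgeR, 0 were higher and 0 lower, and 742 had an unadjusted p under 0.05 (432 higher, 310 lower). DESeq2 called 244 higher and 142 lower, and limma-voom 14 higher and 0 lower. Without Ad-GFP replicate 1, edgeR called 3812 higher and 3689 lower. Leaving out any other single library gave 0 calls.

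Among the fixed lists, camera over all 6 libraries called interferon-stimulated genes (median log2 change 2.45, adjusted p = 2.22e-15) and NF-kB and inflammatory cytokine genes (0.14, adjusted p = 0.000345) as higher. It called cholesterol synthesis (-1.42), fatty acid and triglyceride synthesis (-1.18), nuclear oxidative phosphorylation genes (-2.01), sarcomere and cardiomyocyte markers (-1.44) and fibroblast markers (-0.91) as lower. Every one of these 7 had an adjusted p = 0.648 with an estimated correlation, and adjusted p values of 0.087 to 0.484 with fry. These medians depend on the scaling, the tool and the filter. The NF-kB median was 1.20 with library totals alone, 1.64 with limma-voom, 0.58 with the stricter low-count filter, 0.30 without a filter and 1.37 without Ad-GFP replicate 1, and it turned to -0.15 with median-of-ratios size factors and with DESeq2. Library totals alone gave -0.63 for fatty acid synthesis, -1.22 for oxidative phosphorylation, -0.66 for sarcomere and -0.32 for fibroblast genes. With limma-voom the cholesterol, fatty acid synthesis and fibroblast medians were -0.62, -0.47 and -0.53, and the interferon median was 3.86, against 1.35 with the stricter filter and 5.35 without Ad-GFP replicate 1. Without Ad-RNF128 replicate 3 the sarcomere median was -0.87 and the NF-kB median 0.02, which was 0.09 without Ad-RNF128 replicate 1. The NF-kB, fatty acid synthesis and fibroblast calls ended without Ad-GFP replicate 2 (adjusted p of 0.136, 0.114 and 0.0906) and without Ad-GFP replicate 3 (0.127, 0.127 and 0.0538), where the NF-kB median was -0.07 and -0.02. The fibroblast call also ended with DESeq2 (0.0836) and with the stricter low-count filter (0.096). The sarcomere call ended without Ad-GFP replicate 1 (median -0.57, adjusted p = 0.0982), where the fibroblast median was -0.58. No member of any list passed over all genes. Adjusted over the list alone, 11 of 27 interferon-stimulated, 5 of 21 NF-kB, 15 of 20 oxidative phosphorylation, 2 of 18 cholesterol synthesis, 2 of 22 sarcomere, 0 of 17 fatty acid synthesis and 0 of 13 fibroblast genes passed. Test, median and mean differed in sign for 7 lists, none of them called.

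The following comparisons set the 3 libraries labelled Ad-RNF128 against Ad-GFP replicates 2 and 3, and the 3812 genes that rose and 3689 that fell are 56.9% of 13173 tested. Counts of list members that passed are to be read against this share, since most genes of any kind passed. The sizes were mostly small, since 1102 rose and 499 fell by at least 2-fold. The share of calls that rose was 50.8%, and 69% (5367 higher, 2409 lower) with library totals alone, which moved the median log2 change of all genes from 0.01 to 0.17. With Ad-GFP replicate 1 included, edgeR called 0 genes. In that fit TMM gave this library a factor of 0.47, against 1.08 to 1.22 for the others. The log2 changes and medians over all 6 libraries therefore depend on this scaling as well as on its counts. The composition of the 5 libraries also differed by group. Mitochondrial genome genes took 4.91% and 5.35% of the control counts and 3.08% to 3.32% in Ad-RNF128, ribosomal protein genes 3.55% and 3.86% against 5.14% to 5.48%, and genes without a read numbered 2288 and 2200 against 1190 to 1487.

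Interferon-stimulated genes rose together. All 27 tested members were higher, with a median log2 change of 5.35, and 27 passed adjusted over the list alone. Irf7, a transcription factor that amplifies the interferon response, was at 14.5 and 14.0 CPM in the 2 controls and at 1950 ± 130 (SD, n = 3) in Ad-RNF128 (log2 change 6.95 ± 0.10, edgeR adjusted p = 2.02e-15). Usp18, a negative regulator of interferon signalling, rose by 7.82 ± 0.13, and the antiviral GTPase genes Mx2 and Mx1 by 9.05 ± 0.15 and 9.82 ± 0.19 on the log2 scale. In the 2 controls Mx2 was at 0.775 and 1.22 CPM and Mx1 at 0.111 and 0.141 CPM. With so few control reads the ± of both may understate the counting error. Oas2, a sensor of double-stranded RNA, had 0 control counts and was at least 715-fold higher against a floor of 3 counts over the group. Aim2, a sensor of cytosolic DNA, was at least 270-fold higher on the same floor. The antiviral gene Rsad2 had 3 control counts, and its ratio was 2600 with a counting interval of 889 to 12600. Camera called the list with adjusted p = 2.43e-142, and it held with an estimated correlation (adjusted p = 0.0405). These sizes depend on leaving out Ad-GFP replicate 1, which held Irf7 at 3780 CPM, Usp18 at 399, Bst2 at 1710, Rsad2 at 8.26 and Oas2 at 3.67. With it, the ratio of CPM between the groups was 50.6 for Oas2 and 79.9 for Rsad2. The edgeR log2 changes over all 6 libraries, which rest on TMM scaling, were -0.74 for Irf7, 0.44 for Usp18, 6.18 for Mx2 and 7.39 for Mx1. None passed. The ratio of CPM over all 6 libraries was 1.75 for Irf7 and 3.98 for Usp18, so the sign for Irf7 depends on the scaling.

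Inflammatory genes rose as well. Of 21 NF-kB and cytokine genes, 19 rose and 1 fell, with 20 adjusted over the list alone. Ccl2, a monocyte chemokine, rose by 4.96 ± 0.22 on the log2 scale, Cxcl1, a neutrophil chemokine, by 3.96 ± 0.22, and Relb, an NF-kB subunit, by 2.53 ± 0.12. Cxcl10, an interferon-induced chemokine, rose by 9.17 ± 0.29, from 0.4 and 0.2 CPM. The list median was 1.37, and camera's adjusted p of 9.25e-13 became an adjusted p = 0.19 with an estimated correlation. In the inflammasome and pyroptosis list 4 of 6 genes rose, all 4 also adjusted over the list alone, with Casp4, a pyroptosis caspase, up by 1.42 ± 0.10 (camera adjusted p = 0.0314, and adjusted p = 0.325 with an estimated correlation). Ad-GFP replicate 1 held Relb at 124.7 CPM and Cxcl10 at 146.9 CPM, and over all 6 libraries the log2 changes of Relb, Cxcl10 and Cxcl1 were -2.17, 0.76 and 1.53.

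Lipid synthesis genes fell. All 19 cholesterol synthesis genes fell, 19 also adjusted over the list alone, with a median log2 change of -1.83. Hmgcs1, which makes HMG-CoA, was at 501.0 and 438.4 CPM in the controls and 122 ± 6.08 CPM (SD, n = 3) in Ad-RNF128 (log2 change -2.09 ± 0.07, edgeR adjusted p = 3.53e-12). Insig1, which retains the sterol sensor in the endoplasmic reticulum, fell by 2.18 and Cyp51, a sterol demethylase, by 1.95 on the log2 scale. The list had a camera adjusted p = 3.65e-49, and adjusted p = 0.0404 with an estimated correlation. Of 17 fatty acid and triglyceride synthesis genes 13 fell and 3 rose, 16 adjusted over the list alone, with the desaturase genes Scd2, Scd and Fads2 down by log2 changes of -2.80, -2.50 and -1.69 (camera adjusted p = 3.21e-14, and adjusted p = 0.19 with an estimated correlation). In the fatty acid oxidation list 10 of 24 rose and 3 fell, 13 adjusted over the list alone (camera adjusted p = 0.0314, and adjusted p = 0.314 with an estimated correlation). Cpt1a, which admits long-chain fatty acids to mitochondria, rose by 1.22 ± 0.08, Hadhb by 0.97 ± 0.07, and the lipid droplet gene Plin2 by 0.89 ± 0.06. Plin2 had a log2 change of -0.26 over all 6 libraries, where its ratio of CPM was 1.6. The fatty acid oxidation list had a median of -0.30 over all 6 libraries (0.36 with library totals alone). Without Ad-GFP replicate 1 it was 0.14 (0.30 with library totals alone). Ad-GFP replicate 1 held Hmgcs1 at 1.0 CPM, below every other library.

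**Figure D2:**
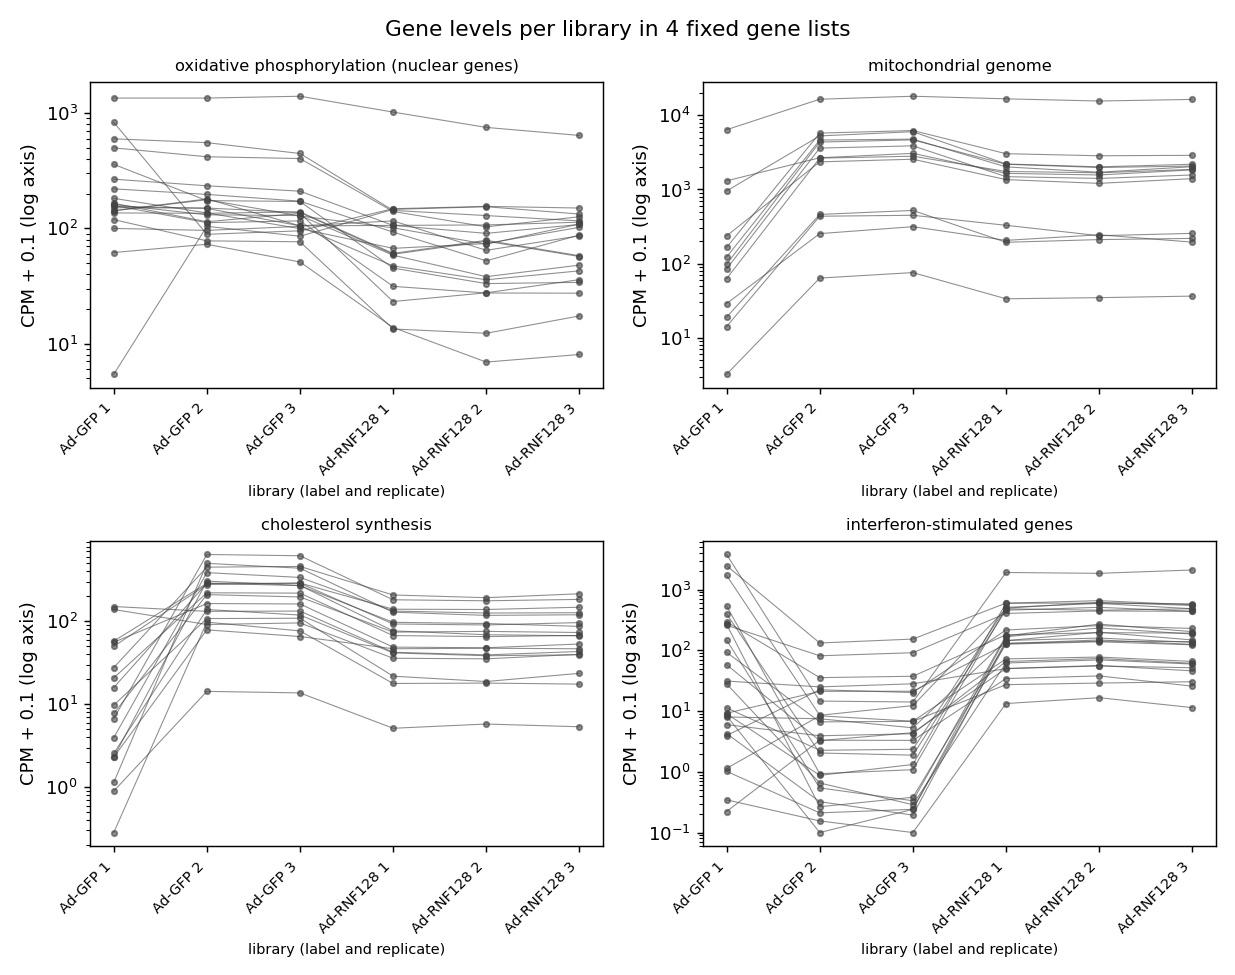
CPM plus 0.1 (log axis) of each gene with a mean of at least 1 CPM in 4 fixed lists, 1 line per gene across the 6 libraries. Most oxidative phosphorylation genes of Ad-GFP replicate 1 lie near those of replicates 2 and 3 (median absolute log2 ratio 0.25), with Cyc1 and Cycs as exceptions. Most mitochondrial genome, cholesterol synthesis and interferon genes of that library lie far from them.

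Mitochondrial respiratory genes fell in the deposited counts, with a limit on the nuclear ones. Of 20 nuclear oxidative phosphorylation genes 18 fell and 2 rose, with 20 adjusted over the list alone and a median log2 change of -1.36 (camera adjusted p = 1.62e-15, and adjusted p = 0.0937 with an estimated correlation). Uqcrc1, a complex III subunit, had a log2 change of -2.15 ± 0.08, Ndufa9, of complex I, -2.59 ± 0.11, and Cox4i1, of complex IV, -2.10 ± 0.09. The 3 values were -2.95, -3.49 and -2.78 over all 6 libraries, and none passed. As a list, the rows of these genes differ from most of the tables. Across the list, counts in Ad-GFP replicate 1 lay within a median absolute log2 ratio of 0.25 of the mean of replicates 2 and 3, against 2.39 over all tested genes. Of 10000 random lists of matched expression 0 were as low. Such closeness is not particular to these rows. Genes chosen after their values were seen also showed it in Ad-GFP replicates 1 to 3, with Myh6 at 16, 13.4 and 11.1 CPM and Myh7 at 13.3, 12.2 and 10.8 CPM. Tnnt2, at 13.3, 342 and 350 CPM, did not. Exceptions within the oxidative phosphorylation list were Cyc1 and Cycs, the 2 members that rose. Ad-GFP replicate 1 held Cyc1 at 832 CPM, against 88.7 and 95.1 in replicates 2 and 3, and Cycs at 5.32 CPM, against 104 and 85.4. The tables are ordered by name except around 2 gene families, where 66 consecutive rows ending at Atp6ap1 are sorted by the count in Ad-GFP replicate 1 and 28 ending at Ndufv2 by that in Ad-GFP replicate 2. Shuffled rows gave runs of at most 12. Nduf genes inside the sorted rows had a median log2 change of 0.16, with 5 of 21 below 0, and those outside -1.15, with 19 of 19 below 0. Atp genes had 0.06 inside, with 15 of 37 below 0, and -1.58 outside, with 15 of 15 below 0. The median absolute log2 ratio of Ad-GFP replicate 1 to replicates 2 and 3 was 1.44 (Nduf) and 3.79 (Atp) inside, against 0.13 and 0.12 outside. These nuclear values are therefore given as deposited, and the same limit applies to Atp6v0d1, a proton pump subunit (log2 change -3.33 ± 0.07, and -3.96 over all 6 libraries), which lies among the unsorted Atp rows. All 13 mitochondrial genome genes fell, along with the lower mitochondrial share of counts given above, 13 also adjusted over the list alone, with a median of -1.16, and -0.66 over all 6 libraries (camera adjusted p = 8.45e-14, and adjusted p = 0.203 with an estimated correlation). Mt-nd4 had a log2 change of -1.49 ± 0.07, and Mt-cyb -1.55 ± 0.08.

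Stress-response genes rose in part. Of 18 NRF2 and antioxidant genes 14 rose and 1 fell, 15 adjusted over the list alone, with Nqo1 up by 1.94 ± 0.09, heme oxygenase Hmox1 by 1.66 ± 0.07 and catalase Cat by 1.49 ± 0.07 (camera adjusted p = 2.68e-08, and adjusted p = 0.19 with an estimated correlation). The log2 changes of Nqo1, Hmox1 and Atf3 over all 6 libraries were -1.48, -0.92 and -0.98, and those of Myc and Ctsl, which kept their sign, 0.02 and 0.79. The medians of the NRF2, autophagy, immediate early and ferroptosis lists there were -0.44, -0.12, -0.21 and -1.23, each opposite in sign to that without Ad-GFP replicate 1. With library totals alone over all 6 libraries, the NRF2, autophagy and immediate early medians were 0.35, 0.31 and 0.33, so their reversal depends on the scaling. Of 20 autophagy and lysosome genes 11 rose and 3 fell, 14 adjusted over the list alone, among them the protease gene Ctsl (1.50 ± 0.07) and the mitophagy receptor gene Bnip3 (1.75 ± 0.08), with camera adjusted p = 0.0032 and adjusted p = 0.325 with an estimated correlation. The autophagy median was 0.27, and 0.43 with library totals alone. Of 11 immediate early genes 7 rose and 2 fell, 9 adjusted over the list alone, with Myc up by 2.91 ± 0.11 and Atf3 by 3.41 ± 0.15 (camera adjusted p = 0.00547, and adjusted p = 0.325 with an estimated correlation). In the ferroptosis list 10 of 14 rose and 2 fell, 12 adjusted over the list alone (camera adjusted p = 0.0284, and adjusted p = 0.203 with an estimated correlation). The genes that fell were the iron importer Tfrc (-1.90 ± 0.11) and Lpcat3 (-1.26 ± 0.08). In the ER stress list 7 of 22 rose and 8 fell, 17 adjusted over the list alone, and camera did not call it (adjusted p = 0.262). Its members Ddit3, a stress-induced transcription factor, and Trib3 rose by 2.24 ± 0.09 and 1.95 ± 0.08, while over all 6 libraries their log2 changes were 0.07 and -2.26. Ad-GFP replicate 1 held Ddit3 at 143 CPM and Myc at 51 CPM, within the range of the libraries labelled Ad-RNF128.

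Most of the matrix and cell cycle genes tested fell, while muscle markers were not called as a list. Of 20 extracellular matrix genes 13 fell and 5 rose, 18 adjusted over the list alone (camera adjusted p = 1.34e-06), and of 13 fibroblast markers 7 fell and 1 rose, 8 adjusted over the list alone (camera adjusted p = 1.91e-05). Both had an adjusted p = 0.19 with an estimated correlation. Col1a1, a fibrillar collagen held by both lists, was at 17700 and 18300 CPM in the controls and 3880 ± 195 CPM (SD, n = 3) in Ad-RNF128 (log2 change -2.37 ± 0.07), and fibrillin Fbn1 fell by 2.09 on the log2 scale. The small proteoglycan gene Fmod had the largest fall named by the rule, -5.16 ± 0.30. Of 24 cell cycle genes 23 fell, 23 adjusted over the list alone (camera adjusted p = 2.68e-07, and adjusted p = 0.19 with an estimated correlation). The list median was -0.54, against -0.26 over all 6 libraries. Bub1b was at -1.05 ± 0.07 and Plk1 at -0.92 ± 0.06, against -0.50 and -0.63 over all 6 libraries. Of 22 sarcomere and cardiomyocyte markers 7 fell and 3 rose, 10 adjusted over the list alone, and camera did not call the list (adjusted p = 0.0982). Cardiac troponin T, Tnnt2, fell by 3.12 on the log2 scale and Tnnc1 by 1.56, while the intermediate filament gene Des rose by 2.91 (-0.50 over all 6 libraries). The skeletal myosin gene Myh2 fell by 5.07 and the growth factor gene Igf2 by 3.58. Vcp, an unfoldase gene, had a log2 change of -3.80 ± 0.11, with 785.1, 611.3 and 480.2 CPM in Ad-GFP replicates 1 to 3. Its spread within groups was large, with a deviance of 18.9 against a median of 1.82 over 1000 genes of like expression, of which 1.3% reached it. Its log2 change over all 6 libraries was -4.63. Ighm and C1qtnf3 had log2 changes of -5.07 and -3.34. Ad-GFP replicate 1 held Fmod, Ighm, Myh2, Igf2, C1qtnf3 and Tnnt2 at 0.245, 0.428, 0, 5.44, 0 and 13.3 CPM. Each lay below the mean in Ad-RNF128, which was 0.534, 0.506, 0.693, 21.7, 1.72 and 44.6 CPM. These falls thus rest on Ad-GFP replicates 2 and 3. Over all 6 libraries the log2 changes were -4.60, -4.49, -4.49, -3.03, -2.78 and -2.60, and none passed. The main heart muscle genes were scarce, with Myh6 at 10.8 to 16 CPM in 5 libraries and 0.104 CPM in Ad-RNF128 replicate 3. The myogenin gene Myog, chosen after its values were seen, was at 33 and 35.4 CPM in Ad-GFP replicates 2 and 3, above Myh6. It was at 3.85 CPM in Ad-GFP replicate 1 and 4.88 to 7.43 CPM in Ad-RNF128. These levels leave the cell type named by the labels unsettled.

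Glycolysis and insulin signalling genes were called by smaller margins. Of 16 glycolysis genes 9 rose and 1 fell, 10 adjusted over the list alone, with the glucose transporter gene Slc2a1 up by 1.33 ± 0.10 (camera adjusted p = 0.0468, and adjusted p = 0.627 with an estimated correlation). This call ended when Ad-GFP replicate 2 (adjusted p = 0.114) or Ad-RNF128 replicate 3 (adjusted p = 0.0744) was also left out. Of 14 insulin signalling genes 9 fell and 2 rose, 12 adjusted over the list alone, with Igfbp5 at -1.94 ± 0.09 (camera adjusted p = 0.0365, and adjusted p = 0.325 with an estimated correlation). It ended when Ad-GFP replicate 3 was also left out (adjusted p = 0.0518). Slc2a1 had a log2 change of 0.26 over all 6 libraries, and there the medians of these lists were -0.66 and 0.05, opposite in sign to -0.22 for insulin signalling and 0.26 for glycolysis. With library totals alone the latter were -0.07 and 0.42, and glycolysis was at 0.14 when Ad-GFP replicate 2 was also left out. Over all 6 libraries the glycolysis median turned to 0.09 with library totals alone. The insulin signalling median there turned to -0.07 with median-of-ratios size factors.

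The other lists tested had camera adjusted p values of 0.27 to 0.894. Among them, hypertrophy-associated genes had 3 up and 4 down of 11, and calcium handling and ion channel genes 5 up and 5 down of 13. Of the latter, Casq2, the sarcoplasmic calcium buffer, was at -1.43 ± 0.07, and at -0.86 over all 6 libraries. Apoptosis genes had 4 up and 6 down of 19, p53 targets 7 up and 4 down of 22, heat shock genes 0 up and 4 down of 9, and proteasome genes 7 up and 3 down of 25. RING ligase relatives and partners of RNF128 had 5 up and 5 down of 16. Markers of other cell types were mixed. Endothelial markers had 4 up and 1 down of 5, smooth muscle and pericyte markers 3 up and 4 down of 11, and macrophage and leukocyte markers 2 up and 0 down of 5. Schwann cell and erythroid markers had 2 tested members each, too few for a list test, with 1 and 0 passing. Adjusted over the list alone, 7, 10, 10, 11, 4, 10, 10, 5, 7, 2, 1 and 0 passed, in the order given. Test, median and mean differed in sign for 5 lists, none of them called.

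**Figure D3:**
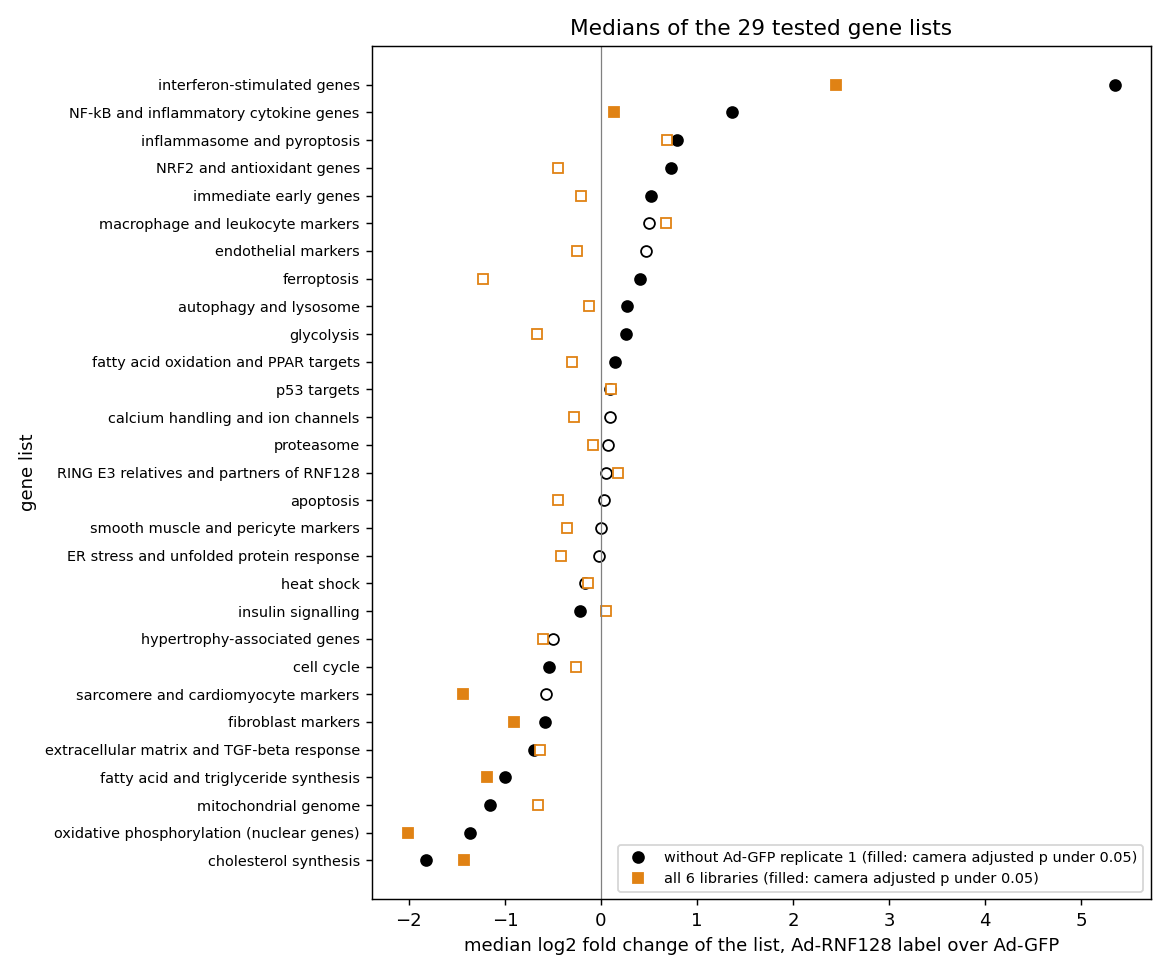
Median log2 fold change (horizontal axis, Ad-RNF128 over Ad-GFP) of the 29 tested lists, without Ad-GFP replicate 1 (circles) and with all 6 libraries (squares), filled where camera's adjusted p was under 0.05. Without that library 9 lists were called higher and 8 lower, and with all 6 libraries 2 higher and 5 lower, among which the NF-kB median lies between -0.15 with median-of-ratios size factors and 1.64 with limma-voom.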

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

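Alternatives for all 6 libraries were planned, apart from those on the comparison without Ad-GFP replicate 1, which were chosen after seeing the data. With all 6 libraries edgeR called 0 genes. Library totals alone gave 8 higher and 0 lower, DESeq2 244 and 142, and limma-voom 14 and 0. Leaving out 1 library gave 0 to 3812 higher and 0 to 3689 lower, both maxima without Ad-GFP replicate 1. Of the lists, 2 were called up and 5 down, against 0 and 0 with an estimated correlation and 1 and 0 with fry. The list called by fry was inflammasome and pyroptosis, which camera did not call, and none of the lists called by camera passed fry. Leaving out 1 library gave 1 to 9 up and 3 to 8 down. The Rnf128 ratio of 1.6 moved between 1.02 and 3.25 with 1 library left out, inside its counting interval. Rnf128 failed both low-count filters, so other scalings and tools gave no value for it.

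Without Ad-GFP replicate 1, edgeR called 3812 genes higher and 3689 lower. Library totals alone gave 5367 and 2409, a log2 change of at least 1 gave 1102 and 499, and all 6 libraries gave 0 and 0. DESeq2 shared 6596 of its 6608 calls with edgeR in gene and direction. Lists numbered 9 up and 8 down, against 1 and 1 with an estimated correlation and 2 and 5 with all 6 libraries. Over all 6 libraries camera's direction turned for 3 called lists, ferroptosis (median -1.23), glycolysis (-0.66) and insulin signalling (0.05). The median alone turned for NRF2 (-0.44), fatty acid oxidation (-0.30), autophagy (-0.12) and immediate early genes (-0.21). With library totals alone over all 6 libraries these medians were 0.35, 0.36, 0.31 and 0.33, and the glycolysis median was 0.09. The 23 named genes that changed sign had log2 changes of -0.73 (Oas1i), -0.26 (Plin2), -2.26 (Trib3), -0.98 (Atf3), -0.74 (Irf7), -2.17 (Relb), -1.09 (Pycard), -2.71 (Phlda3), 0.07 (Ccng1), -0.92 (Hmox1), -1.48 (Nqo1), -1.68 (Sqstm1), -1.53 (Tpi1), 0.12 (Pik3ca), -0.50 (Des), -0.09 (Rcan1), -1.35 (Jph2), -2.25 (Egfl7), -0.25 (Vwf), 0.18 (Hsp90aa1), -1.63 (Psmc3), 0.24 (Psmd1) and 0.01 (Nedd4). These fits differ by the sample left out and by the scaling that goes with it. The cause of its values was not tested here. By the ratio of CPM over all 6 libraries, Oas1i (1.77), Plin2 (1.6), Atf3 (1.42), Irf7 (1.75) and Pycard (1.06) still rose. The same held for Hmox1 (1.29), Des (1.86), Rcan1 (1.7) and Vwf (1.43), so these signs depend on the scaling. The other listed genes turned in that ratio too. Same-numbered samples had correlations of -0.178, 0.0131 and -0.136 in their deviations from the group means. These cannot show or exclude a pairing, because Ad-GFP replicate 1 shapes the deviations of all 3 controls. With Ad-RNF128 replicate 1 its correlation was -0.178, and those of Ad-GFP replicates 2 and 3 were 0.181 and 0.171. The replicate block left the count at 0 and 0 with all 6 libraries, where it moved the list medians to 1.56 (NF-kB), 3.89 (interferon), -0.78 (cholesterol), -0.50 (fatty acid synthesis) and -0.54 (fibroblast). It gave 3931 higher and 3864 lower without Ad-GFP replicate 1, where the ferroptosis list (adjusted p = 0.0524) and Vwf (adjusted p = 0.0503) lost their calls.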

Other observations

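The tests on depth and on the most abundant genes were set before their results were seen, and the other tests of this part were chosen after the result was seen. Over all 6 libraries, 10 splits into groups of 3 exist, too few for a share under 0.05. The real split called 0 genes, the highest of the other splits called 0, and all 10 gave at least as many as the real one. With 0 calls in the real split that outcome was fixed in advance, so the comparison decides nothing.

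Rnf128 was at 0 to 3 counts in every library, while Rnf157 was high in the libraries labelled Ad-RNF128. Swapped group labels stay open, because the highest Rnf128 count in Ad-GFP was 2 and no library of either group holds enough Rnf128 counts to decide. A construct of another species or with a recoded sequence may escape counting on the rat gene, and the group ratio of 1.6 leaves that open, since no reads or vector sequence were used here. A vector that carries Rnf157 is another hypothesis. The lowest Rnf157 level of the libraries labelled Ad-RNF128 was 47.6 times the highest of Ad-GFP, which induction of the cells' own gene would also give, so these cannot be told apart. The labels' protocols also write RNF28, another name of Trim63, and a vector with the rat Trim63 sequence is argued against, since the lowest Trim63 level of the libraries labelled Ad-RNF128 was 0.897 times the highest of Ad-GFP.

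Nuclear oxidative phosphorylation genes were lower in the libraries labelled Ad-RNF128. Library scaling is argued against, because the list median stayed at -1.20 with library totals alone. A candidate explanation is that values of these rows were set apart from the rest of the tables after counting: the median absolute log2 ratio of Ad-GFP replicate 1 to the other controls was 0.25 over the list, where matched random lists had a median of 2.46 and a minimum of 0.66. The rows sorted by count lie around the Atp and Nduf names and hold 0 of the 20 list members. Members such as the Sdh, Uqcr and Cox genes lie elsewhere by name. The tables do not show how the sorted rows or these values arose. An effect of the vector on the cells stays open, although Nduf genes inside the sorted run had a median log2 change of 0.16. There 5 of 21 were below 0, against 19 of 19 outside it. The raw reads would be needed to tell these explanations apart.

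Ad-GFP replicate 1 stood apart from the other libraries. Lower depth is argued against, since the other libraries thinned to its total had at most 2493 genes without a read, against 3551 in it. Its highest correlation was 0.816 without the 100 most abundant genes. A rank correlation hardly depends on so few genes, so that test decides nothing about them. A few genes did not take most of its counts, since its 10 highest took 11.7%, against 5.78% to 10.1% in the other libraries. A library of the other group under a wrong label is argued against by its Rnf157 level of 22.3 CPM, far below 1920 CPM. No biological explanation was tested, and another origin or handling of that sample stays open.

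The one value that is not whole, 344.5 for the top row in Ad-GFP replicate 1, equals the mean of 324 and 365 in Ad-GFP replicates 2 and 3. Myh7 was at 10.2 to 13.6 CPM in 5 libraries and 0.0519 CPM in Ad-RNF128 replicate 3, and Actc1 at 9.84 to 17.5 CPM and 0.26 CPM. Imprinted H19 was at 1900 and 2120 CPM in Ad-GFP replicates 2 and 3, 607 CPM in Ad-GFP replicate 1, and 477 to 517 CPM in Ad-RNF128. These genes were chosen after their values were seen.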
